A study of Homo sapiens with 12 samples.

How the data were processed

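Messenger RNA of the cholangiocarcinoma line TFK1 was sequenced in 12 samples, 3 biological replicates each of untreated control, radiation (6 Gy), nab-paclitaxel (1.62 ng/ml) and both, per the labels. Per the labels' protocols the cells grew in RPMI 1640, RNA was taken 24 h after treatment and checked on a Bioanalyzer, and libraries were made with a SMARTer mRNA-seq kit. The reference build was hg38, per the submitters' processing notes. The aligner, the counting tool and their versions are not given in the sources used here. Whether counting used the strand is not stated either, so antisense and overlapping genes are uncertain.

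The authors deposited 1 table of FPKM values, per the file headers, with 58735 genes (19951 protein coding), their lengths and 12 sample columns. All gene identifiers were found in GENCODE release 29. How gene length was made is not stated. Multiplying FPKM by gene length gave, in every library, whole multiples of 1 step for 100% of genes (within 0.05), so fragment numbers could be recovered. The deposited FPKM values were found to be scaled by a median-of-ratios size factor of each library times the geometric mean of the 12 library totals, and not by the library's own total. Recovered totals per library in the order of replicates 1, 2 and 3 were 15650154, 15864937 and 14840283 in control, 16219617, 16809052 and 16539323 in radiation, 17080792, 17405961 and 17992242 in nab-paclitaxel, and 17130596, 16057485 and 16993592 in the combination.

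Groups were taken from the labels. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and 1 spread shared by the 4 groups, on the 13609 genes with a mean of at least 1 FPKM over the 12 libraries. It had 8 residual and 3.39 prior degrees of freedom. The contrasts were radiation vs control, nab-paclitaxel vs control, combination vs control, combination vs radiation, combination vs nab-paclitaxel, and the interaction, with a moderated F test over the groups. Tests were two-sided, p was adjusted by Benjamini-Hochberg within each contrast, and the threshold was an adjusted p of 0.05. No replicate block was used. Deviations from the group means correlated above 0.1 in all 3 same-numbered pairs of control and combination (r = 0.233, 0.543 and 0.172), and the labels tie the numbers to no shared batch or day. Apart from the tests, subsets and settings named as chosen later, the tests, filter, gene lists, the rule for named genes and the alternatives listed below were fixed before the data were examined.

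Gene lists were tested with limma's camera with its preset correlation of 0.01 and adjusted over the 24 of 27 lists that had at least 5 tested members. The lists cover p53 targets, homologous recombination and Fanconi, end joining, checkpoint signalling, replication, mitosis, tubulin and microtubules, histones, interferon-stimulated genes, NF-kB targets, senescence-associated secreted genes and macrophage-directed signals. They also cover apoptosis, unfolded protein and integrated stress responses, heat shock, cholesterol synthesis, hypoxia and glycolysis, antigen presentation, epithelial-mesenchymal transition, biliary genes, paclitaxel transport, oxidative stress, mitochondrial mRNAs and ribosomal proteins. The remaining 3 hold macrophage, fibroblast, and lymphocyte and endothelial markers, of which too few members were expressed for a test. Some genes belong to more than 1 list.

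Genes were named by rule. For each comparison these were the 10 largest rises and 10 largest falls (5 and 5 for combination vs nab-paclitaxel and the interaction) among genes past the threshold with a mean of at least 2 FPKM in the higher group and no overlap between groups. Where none passed, the 3 with the smallest p in that direction were taken. From each list up to 4 genes past the threshold with the smallest p were added, or otherwise the 2 with the highest expression. ACTB, GAPDH, CDKN1A, MDM2 and GDF15 were always included. Some names were left out for length, and a few genes that the rule picks are not reported here.

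Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, size factors over tested genes, TPM scaling, quantile normalization, the replicate number as a block, no trend, protein-coding genes only, limma's voom on recovered fragments, only the 2 groups compared, camera with an estimated correlation or on ranks, fry, and leaving out each library. Further alternatives are given with their effect in the closing section. The fit was tested on simulated data with the real libraries' means and sizes over 13624 genes. Changes of 0.5, 1 and 2 on the log2 scale were called in 25.9%, 70.4% and 100% of genes for radiation vs control, and in 22.5%, 75% and 100% for combination vs radiation. For combination vs control these shares were 25.4%, 85.1% and 100%, and no change was called with the wrong sign. Of 20 lists without a change 0 were called. The simulated genes varied independently of each other, so this does not test camera on lists whose genes correlate. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.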

Results

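Messenger RNA was sequenced from TFK1, an established human cholangiocarcinoma cell line, 24 h after treatment. The labels ask how nab-paclitaxel, an albumin-bound form of the microtubule-stabilising drug paclitaxel, makes these cells more sensitive to radiation. The 12 libraries fell into 4 groups of 3 labelled biological replicates: untreated control, radiation (6 Gy), nab-paclitaxel (1.62 ng/ml) and the combination of both. Expression was deposited as FPKM for 58735 genes, of which 13609 had a mean of at least 1 over the libraries and were tested. The values correspond to 14840283 to 17992242 fragments per library. Values after ± are SE for log2 fold changes on log2(FPKM + 1) and SD for FPKM, with n = 3 libraries per group. A gene rose or fell where limma gave an adjusted p under 0.05. In each gene named with such a change, all 3 libraries of one group lay above all 3 of the other, which chance gives for 10% of genes. Lists of genes are given with the median log2 fold change of their tested members, to which fits without the filter add members under 1 FPKM.

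In a principal component analysis, component 1 (28.9% of variance) was negative in the 6 libraries without drug and positive in the 6 with drug. On component 2 (22.01%) control 2 stood at 30.6, nab-paclitaxel 1 at 28.6 and combination 2 at 3.64, each the highest of its group. The deviations of these 3 deviating libraries from their groups correlated across genes, and fits without them were chosen after seeing the data. The r was 0.463 for control 2 and nab-paclitaxel 1, 0.543 for control 2 and combination 2, and 0.332 for nab-paclitaxel 1 and combination 2. Genes are not independent replicates, so no p is given.

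**Figure D1:**
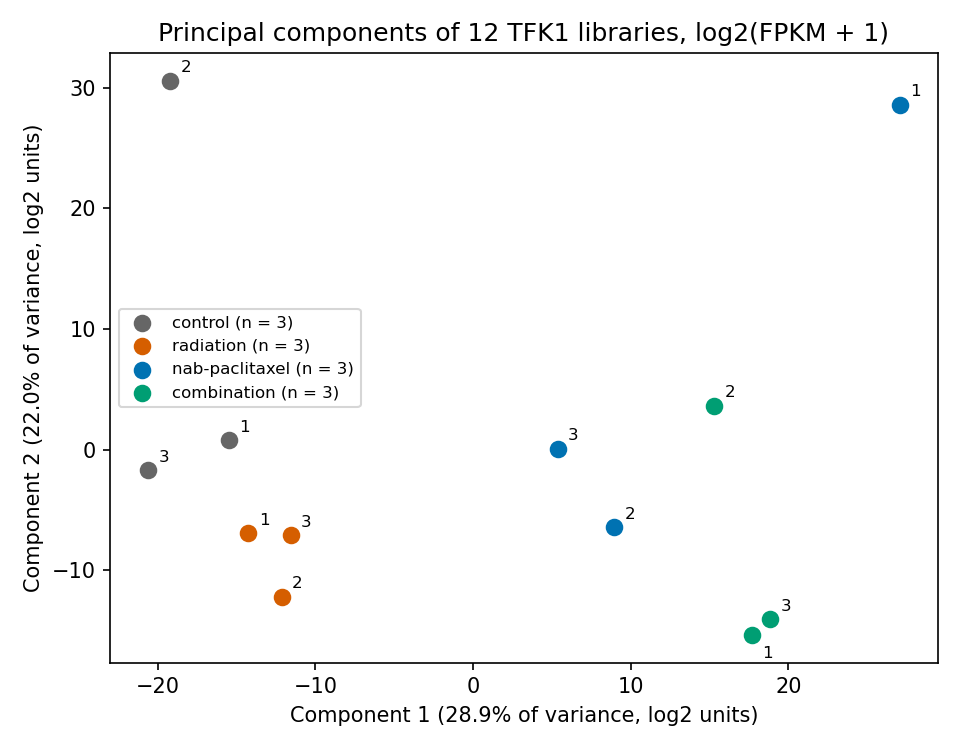
Scores of the 12 libraries on components 1 and 2, in log2(FPKM + 1) units, coloured by treatment (n = 3 each) with the replicate number beside each point. Component 1 (28.9% of variance) separates the 6 drug-treated libraries from the 6 others, and control 2 and nab-paclitaxel 1 stand highest on component 2 (22.01%).

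Markers of other cell types were low. Of 19 macrophage markers only ITGAX reached a mean of 1 FPKM (1.90). Of 15 fibroblast markers 4 did, COL1A1 being the highest (5.70), and of 15 lymphocyte and endothelial markers 0 did. Mitochondrially encoded mRNAs took 12.1 ± 1.28% of fragments in control, 13.1 ± 0.627% in radiation, 10.6 ± 1.39% in nab-paclitaxel and 11.6 ± 1.59% in the combination. The common reference genes were not constant. ACTB fell with radiation (-0.41 ± 0.08) and rose with nab-paclitaxel (0.47 ± 0.08). GAPDH rose with nab-paclitaxel (0.56 ± 0.11). These 3 calls were lost under quantile normalization (adjusted p = 0.180, 0.104 and 0.0785). The fall of ACTB with radiation was also lost without control 1 (adjusted p = 0.0519) or without radiation 1, 2 or 3 (adjusted p = 0.0612, 0.0760 and 0.0664).

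Radiation against control gives the response to 6 Gy alone. 28 of 39 DNA replication genes, 28 of 40 mitotic genes and 11 of 30 homologous recombination and Fanconi genes fell, and 13 of 37 p53 target genes and 7 of 11 histone genes rose. CDKN1A, which encodes the cell cycle inhibitor p21, went from 117 ± 7.82 to 199.8 ± 4.44 FPKM (0.77 ± 0.08, adjusted p = 4.89e-04). MCM3, a subunit of the replicative helicase, went from 34.5 ± 1.66 to 19.5 ± 0.846 FPKM (-0.79 ± 0.08, adjusted p = 4.34e-04). HIST1H2BD, a histone H2B gene, went from 23.4 ± 2.37 to 52.6 ± 0.495 FPKM (1.14 ± 0.09, adjusted p = 1.17e-04).

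Among p53 targets, the polo-like kinase PLK2 (1.04 ± 0.07), the autophagy factor TP53INP1 (0.96 ± 0.11) and the p53 phosphatase PPM1D (0.59 ± 0.07) rose. MDM2 (0.03 ± 0.12, adjusted p = 0.935) and GDF15 (-0.22 ± 0.12, adjusted p = 0.348) did not pass. Of the 37 p53 target genes 13 rose, 0 fell and 24 did not pass, with 22 up and 1 down adjusted over the list alone. The p53 target list had a median of 0.37 (camera adjusted p = 2.33e-15). Of the 11 replication-dependent histone genes 7 rose, 0 fell and 4 did not pass, with 10 up and 1 down adjusted over the list alone. The replication-dependent histone list had a median of 0.63 (camera adjusted p = 4.02e-12). Histone genes have near-identical copies, so the values of single members are uncertain. The level of histone mRNAs in these libraries also depends on how poly(A) RNA was selected. The licensing factor CDT1 (-1.03 ± 0.11), the replication factor MCM10 (-0.78 ± 0.09) and the ribonucleotide reductase subunit RRM2 (-1.04 ± 0.16) fell. Of the 39 DNA replication genes 0 rose, 28 fell and 11 did not pass, with 0 up and 34 down adjusted over the list alone. The DNA replication list had a median of -0.56 (camera adjusted p = 4.84e-28). Among mitotic genes, the ubiquitin-conjugating enzyme UBE2C (-1.09 ± 0.11), the survivin gene BIRC5 (-0.93 ± 0.09) and CDC20, the activator of the anaphase-promoting complex (-0.73 ± 0.08), fell. Of the 40 mitotic genes 0 rose, 28 fell and 12 did not pass, with 0 up and 35 down adjusted over the list alone. The mitotic list had a median of -0.62 (camera adjusted p = 1.14e-29). BRCA1 (-0.90 ± 0.10), FANCD2 (-0.69 ± 0.09) and RAD54L (-0.81 ± 0.11), which act in DNA crosslink and break repair, fell. Of the 30 homologous recombination and Fanconi genes 0 rose, 11 fell and 19 did not pass, with 0 up and 15 down adjusted over the list alone. The homologous recombination and Fanconi list had a median of -0.37 (camera adjusted p = 6.78e-12). The fork protection factor TIMELESS fell (-0.72 ± 0.13). Of the 23 checkpoint signalling genes 0 rose, 7 fell and 16 did not pass, with 0 up and 14 down adjusted over the list alone. The checkpoint signalling list had a median of -0.34 (camera adjusted p = 5.21e-08).

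Endoplasmic reticulum and amino acid stress genes fell with radiation, among them the pseudokinase TRIB3 (-0.79 ± 0.10), PCK2 (-0.71 ± 0.10) and HERPUD1 (-0.57 ± 0.09). The transcription factor ATF3, of the same list, rose (0.56 ± 0.07). Of the 29 unfolded protein and integrated stress response genes 1 rose, 14 fell and 14 did not pass, with 1 up and 26 down adjusted over the list alone. This list had a median of -0.41 (camera adjusted p = 9.07e-15). OASL, an interferon-induced gene, rose (0.75 ± 0.08). Of the 29 interferon-stimulated genes 3 rose, 1 fell and 25 did not pass, with 4 up and 1 down adjusted over the list alone. The interferon-stimulated list had a median of 0.10 (camera adjusted p = 0.00586, adjusted p = 0.133 with an estimated correlation). The matrix protein CTGF rose (0.83 ± 0.11), and EREG, a ligand of the epidermal growth factor receptor, fell (-1.31 ± 0.16). Further lists past the threshold were senescence-associated genes (6 rose, 2 fell, median 0.17, camera adjusted p = 0.00364, adjusted p = 0.171 with an estimated correlation), biliary epithelial genes (2 rose, 0 fell, median 0.41, camera adjusted p = 0.00536, adjusted p = 0.115 with an estimated correlation) and cytosolic ribosomal protein genes (0 rose, 5 fell, median -0.32, camera adjusted p = 3.92e-11, adjusted p = 0.294 with an estimated correlation). The end joining list did not pass (camera adjusted p = 0.251), with XRCC6 at -0.14 ± 0.08 and XRCC5 at -0.27 ± 0.10, neither past the threshold. Outside the lists, the carboxypeptidase CPA4 had the largest rise, from 2.61 ± 0.468 to 13.1 ± 0.420 FPKM (1.98 ± 0.10). KRTAP2-3 rose too (1.68 ± 0.13), but it has the near-identical copy KRTAP2-4 and is uncertain. The guidance cue SEMA3A (-1.27 ± 0.16), the kinase subunit PRKACB (-1.14 ± 0.19) and the chromatin protein HMGB2 (-1.04 ± 0.12) fell. Senescence-associated genes had a median of 0.07 without the filter, and lost their call by camera on ranks (adjusted p = 0.106). Biliary epithelial genes had a median of 0.03 without the filter, 0.26 without the 3 deviating libraries and 0.26 without control 2, and lost their call by camera on ranks (adjusted p = 0.0814). Cytosolic ribosomal protein genes had a median of -0.14 under quantile scaling.

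In total 807 genes changed with radiation, 337 higher and 470 lower, of which 38 by at least 1 on the log2 scale. The 41.8% that were higher became 49.9% under quantile normalization. The number was 476 without control 1, 337, 320 and 329 without radiation 1, 2 and 3, and 1305 without nab-paclitaxel 1. It was 2947 without the 3 deviating libraries, chosen after seeing the data.

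**Figure D2:**
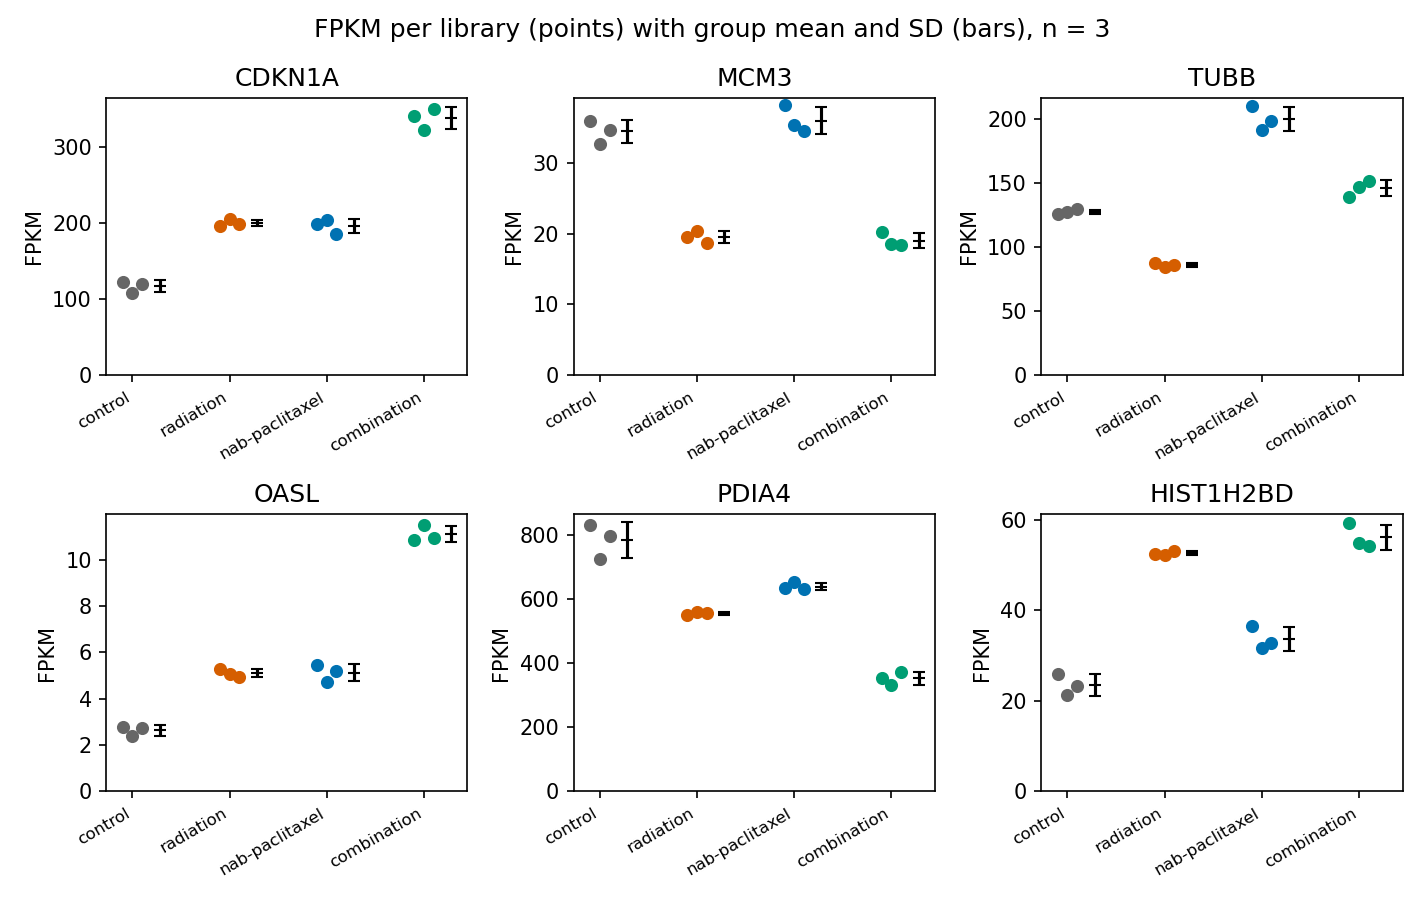
FPKM of CDKN1A, MCM3, TUBB, OASL, PDIA4 and HIST1H2BD in each library (points, coloured by group) with group means and SD (n = 3), on axes from 0. CDKN1A and OASL are highest in the combination (338 ± 14.2 and 11.1 ± 0.352 FPKM), TUBB is highest with nab-paclitaxel alone (200.4 ± 9.28 FPKM) and PDIA4 is lowest in the combination (352 ± 20.9 FPKM).

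In genome build hg38 these genes are CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), MCM3 (ENSG00000112118, chromosome 6, 52264009 to 52284881), TUBB (ENSG00000196230, chromosome 6, 30720201 to 30725426), OASL (ENSG00000135114, chromosome 12, 121019111 to 121039242), PDIA4 (ENSG00000155660, chromosome 7, 149003062 to 149028641) and HIST1H2BD (ENSG00000158373, chromosome 6, 26158146 to 26171349).

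Nab-paclitaxel against control gives the response to the drug alone. 11 of 27 tubulin and microtubule genes, 11 of 29 interferon-stimulated genes and 8 of 26 genes of cholesterol synthesis rose. The beta-tubulin gene TUBB went from 127 ± 1.95 to 200.4 ± 9.28 FPKM (0.65 ± 0.07, adjusted p = 8.21e-04). ISG15, a ubiquitin-like modifier, went from 51.4 ± 8.79 to 105 ± 16.4 FPKM (1.02 ± 0.15, adjusted p = 0.00400). CDKN1A rose to 195.8 ± 9.80 FPKM (0.74 ± 0.08, adjusted p = 8.21e-04).

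The other tubulin genes that rose included TUBB4B (0.92 ± 0.11), TUBA1C (0.81 ± 0.09) and TUBB2A (1.04 ± 0.17). Of the 27 tubulin and microtubule genes 11 rose, 1 fell and 15 did not pass, with 14 up and 1 down adjusted over the list alone. The tubulin and microtubule list had a median of 0.28 (camera adjusted p = 1.19e-05). Within that list the 10 alpha- and beta-tubulin genes, a subset chosen after seeing the data, had a median of 0.79 against 0.14 for the other 17. CDC20 (0.76 ± 0.08), the kinesin KIF20A (0.77 ± 0.11) and the spindle checkpoint kinase BUB1 (0.57 ± 0.10) rose. Of the 40 mitotic genes 16 rose, 2 fell and 22 did not pass, with 17 up and 3 down adjusted over the list alone. The mitotic list had a median of 0.31 (camera adjusted p = 1.19e-05, adjusted p = 0.147 with an estimated correlation). PLK2 (0.70 ± 0.07), the mitochondrial reductase FDXR (0.79 ± 0.10) and the antiproliferative gene BTG2 (0.68 ± 0.09) rose. Of the 37 p53 target genes 7 rose, 0 fell and 30 did not pass, with 9 up and 0 down adjusted over the list alone. The p53 target list had a median of 0.19 (camera adjusted p = 4.50e-04). MDM2 (-0.06 ± 0.12, adjusted p = 0.788) and GDF15 (-0.13 ± 0.12, adjusted p = 0.499) did not pass. OASL (0.76 ± 0.08) and the ISG15 ligase HERC5 (0.74 ± 0.12) rose. Of the 29 interferon-stimulated genes 11 rose, 0 fell and 18 did not pass, with 15 up and 1 down adjusted over the list alone. The interferon-stimulated list had a median of 0.34 (camera adjusted p = 9.84e-07). Squalene synthase FDFT1 (0.82 ± 0.08) and the sterol sensor INSIG1 (0.89 ± 0.14) rose. Of the 26 cholesterol synthesis genes 8 rose, 0 fell and 18 did not pass, with 16 up and 0 down adjusted over the list alone. The cholesterol synthesis list had a median of 0.37 (camera adjusted p = 9.84e-07). The chaperones HSP90AB1 (0.54 ± 0.08) and HSPA1B (0.65 ± 0.12) rose. Of the 13 heat shock genes 6 rose, 0 fell and 7 did not pass, with 8 up and 0 down adjusted over the list alone. The heat shock list had a median of 0.44 (camera adjusted p = 1.19e-05). Tubulin and microtubule genes had a median of 0.13 under quantile scaling. Interferon-stimulated genes had a median of 0.16 without the filter.

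The glycolytic enzymes LDHA (0.78 ± 0.11) and PGK1 (0.50 ± 0.08) rose. Of the 25 hypoxia and glycolysis genes 8 rose, 0 fell and 17 did not pass, with 11 up and 1 down adjusted over the list alone. The hypoxia and glycolysis list had a median of 0.25 (camera adjusted p = 7.03e-05). NFKBIE, an inhibitor of NF-kB, rose (0.67 ± 0.10). Of the 16 NF-kB target and cytokine genes 3 rose, 0 fell and 13 did not pass, with 5 up and 0 down adjusted over the list alone. The NF-kB target and cytokine list had a median of 0.30 (camera adjusted p = 6.77e-04). ANGPTL4, a lipase inhibitor (1.56 ± 0.18), and the urokinase receptor PLAUR (0.73 ± 0.12) rose. Of the 17 senescence-associated genes 8 rose, 0 fell and 9 did not pass, with 10 up and 0 down adjusted over the list alone. The senescence-associated list had a median of 0.35 (camera adjusted p = 7.00e-06). Superoxide dismutase SOD1 (0.65 ± 0.12) and catalase CAT (0.46 ± 0.08) rose. Of the 25 oxidative stress response genes 7 rose, 1 fell and 17 did not pass, with 9 up and 1 down adjusted over the list alone. The oxidative stress response list had a median of 0.28 (camera adjusted p = 4.86e-05, adjusted p = 0.0751 with an estimated correlation). Asparagine synthetase ASNS (-1.09 ± 0.12) and EDEM1 (-0.55 ± 0.08), which acts in the disposal of misfolded proteins, fell. Of the 29 unfolded protein and integrated stress response genes 1 rose, 8 fell and 20 did not pass, with 1 up and 12 down adjusted over the list alone. This list had a median of -0.24 (camera adjusted p = 9.84e-07). The remaining lists past the threshold were replication-dependent histone genes (4 rose, 1 fell, median 0.34, camera adjusted p = 0.00252), DNA replication genes (8 rose, 0 fell, median 0.17, camera adjusted p = 6.77e-04, adjusted p = 0.0545 with an estimated correlation) and biliary epithelial genes (5 rose, 0 fell, median 0.22, camera adjusted p = 0.00587, adjusted p = 0.0861 with an estimated correlation). NF-kB target and cytokine genes had a median of 0.11 without the filter. Senescence-associated genes had a median of 0.17 without the filter, 0.17 under quantile scaling and 0.20 without nab-paclitaxel 1. Oxidative stress response genes had a median of 0.15 under quantile scaling. Unfolded protein and integrated stress response genes had a median of -0.42 under quantile scaling. Replication-dependent histone genes had a median of 0.52 with a pseudocount of 0.1, 0.13 without the filter and 0.52 by voom. DNA replication genes had a median of 0.11 under quantile scaling. Biliary epithelial genes had a median of 0.02 without the filter and 0.15 without the 3 deviating libraries, and lost their call with a filter of 5 FPKM (adjusted p = 0.0631).

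The calls of 4 further lists rested on single libraries. Of the 22 antigen presentation genes 6 rose, 1 fell and 15 did not pass, with 9 up and 1 down adjusted over the list alone. The antigen presentation list had a median of 0.26 (camera adjusted p = 0.0221, adjusted p = 0.256 with an estimated correlation). This call was lost without control 2 (adjusted p = 0.145) or nab-paclitaxel 2 (adjusted p = 0.0648). Of the 30 homologous recombination and Fanconi genes 0 rose, 1 fell and 29 did not pass, with 0 up and 1 down adjusted over the list alone. The homologous recombination and Fanconi list had a median of -0.07 (camera adjusted p = 0.0226, adjusted p = 0.417 with an estimated correlation). It was not called without control 2 (adjusted p = 0.221) or nab-paclitaxel 2 (adjusted p = 0.174). Of the 13 mitochondrially encoded mRNA genes 0 rose, 0 fell and 13 did not pass, with 0 up and 0 down adjusted over the list alone. The mitochondrially encoded mRNA list had a median of -0.18 (camera adjusted p = 0.0322, adjusted p = 0.541 with an estimated correlation). Without control 2, nab-paclitaxel 2 or nab-paclitaxel 3 this too was not called (adjusted p = 0.354, 0.363 and 0.0707). Of the 49 cytosolic ribosomal protein genes 0 rose, 0 fell and 49 did not pass, with 0 up and 0 down adjusted over the list alone. The cytosolic ribosomal protein list had a median of 0.17 (camera adjusted p = 0.00153, adjusted p = 0.541 with an estimated correlation). The ribosomal call was lost without nab-paclitaxel 1 (adjusted p = 0.586), and the median was -0.03 under quantile normalization. That normalization also ended the calls for mitochondrial (adjusted p = 0.673), homologous recombination (adjusted p = 0.166), antigen presentation (adjusted p = 0.158) and biliary genes (adjusted p = 0.0800). Antigen presentation genes had a median of 0.11 without the 3 deviating libraries, and lost their call with a filter of 5 FPKM (adjusted p = 0.0631). Homologous recombination and Fanconi genes had a median of -0.10 with tested-gene size factors, -0.11 without control 1, -0.15 without control 3 and -0.17 without nab-paclitaxel 1. The homologous recombination and Fanconi genes lost their call with a filter of 5 FPKM and by fry (adjusted p = 0.0631 and 0.211). Mitochondrially encoded mRNA genes had a median of -0.29 without nab-paclitaxel 1, and lost their call without the filter and by fry (adjusted p = 0.432 and 0.369). Cytosolic ribosomal protein genes lost their call with a filter of 5 FPKM, without the 3 deviating libraries and by fry (adjusted p = 0.0693, 0.815 and 0.172).

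Among the 10 largest rises were SFN, which encodes 14-3-3 sigma (1.54 ± 0.16), the vitamin D hydroxylase CYP24A1 (1.06 ± 0.08), the arrestin-like ARRDC3 (1.06 ± 0.11) and the retinal dehydrogenase ALDH1A3 (0.96 ± 0.07). The 10 largest falls were small RNA genes, pseudogenes or an antisense gene. SNORD11 (-2.34 ± 0.39), for example, rests on 49 fragments over the 12 libraries. In total 1200 genes changed with nab-paclitaxel, 736 higher and 464 lower, of which 64 by at least 1 on the log2 scale. The 61.3% that were higher became 49.3% with size factors from the tested genes and 48.3% under quantile normalization. The number of genes was 783 and 524 without control 1 and 3, 725, 717 and 749 without radiation 1, 2 and 3, and 718 and 638 without nab-paclitaxel 1 and 2. It was 8 with only these 2 groups in the fit, 579 without the expression filter and 789 under quantile normalization. It was 1836 without the 3 deviating libraries, chosen after seeing the data.

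The combination against control gives the state reached with both treatments. CDKN1A reached 338 ± 14.2 FPKM against 117 ± 7.82 in control (1.53 ± 0.08, adjusted p = 9.31e-07). PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, fell from 783 ± 55.1 to 352 ± 20.9 FPKM (-1.15 ± 0.08, adjusted p = 1.21e-05). OASL rose from 2.62 ± 0.218 to 11.1 ± 0.352 FPKM (1.74 ± 0.08, adjusted p = 3.27e-07). The stress response list had the lowest median of the 24 lists and histone genes the highest.

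TRIB3 (-1.40 ± 0.10), PCK2 (-1.04 ± 0.10), the chaperone DNAJB11 (-0.84 ± 0.07) and the cystine transporter SLC7A11 (-1.67 ± 0.18) fell. Of the 29 unfolded protein and integrated stress response genes 1 rose, 26 fell and 2 did not pass, with 1 up and 27 down adjusted over the list alone. This list had a median of -0.79 (camera adjusted p = 2.13e-17). FDXR (1.43 ± 0.10), PLK2 (1.36 ± 0.07) and BTG2 (1.28 ± 0.09) rose. Of the 37 p53 target genes 26 rose, 2 fell and 9 did not pass, with 28 up and 3 down adjusted over the list alone. The p53 target list had a median of 0.56 (camera adjusted p = 2.25e-12). GDF15 fell (-0.52 ± 0.12), a call lost without the expression filter (adjusted p = 0.0794), and MDM2 (-0.06 ± 0.12, adjusted p = 0.751) did not pass. ISG15 (1.72 ± 0.15), the interferon-induced IFIT2 (1.23 ± 0.09) and HERC5 (1.22 ± 0.12) rose. Of the 29 interferon-stimulated genes 19 rose, 0 fell and 10 did not pass, with 20 up and 0 down adjusted over the list alone. The interferon-stimulated list had a median of 0.56 (camera adjusted p = 5.41e-11). HIST1H2BD rose by 1.23 ± 0.09. Of the 11 replication-dependent histone genes 9 rose, 1 fell and 1 did not pass, with 9 up and 1 down adjusted over the list alone. The replication-dependent histone list had a median of 0.76 (camera adjusted p = 3.44e-06). TUBB2A (1.31 ± 0.17) and TUBA4A (1.04 ± 0.11) rose. Of the 27 tubulin and microtubule genes 9 rose, 1 fell and 17 did not pass, with 10 up and 1 down adjusted over the list alone. The tubulin and microtubule list had a median of 0.16 (camera adjusted p = 0.00601). Interferon-stimulated genes had a median of 0.24 without the filter. Replication-dependent histone genes had a median of 0.26 without the filter.

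The transcription factor E2F1 (-1.22 ± 0.11), CDT1 (-1.17 ± 0.11) and MCM3 (-0.83 ± 0.08) fell. Of the 39 DNA replication genes 2 rose, 26 fell and 11 did not pass, with 2 up and 29 down adjusted over the list alone. The DNA replication list had a median of -0.46 (camera adjusted p = 4.13e-12). The centromere protein CENPF (-1.04 ± 0.11) and the kinesin KIF14 (-1.02 ± 0.15) fell. Of the 40 mitotic genes 0 rose, 16 fell and 24 did not pass, with 0 up and 19 down adjusted over the list alone. The mitotic list had a median of -0.30 (camera adjusted p = 1.15e-07, adjusted p = 0.0951 with an estimated correlation). BRCA1 (-0.98 ± 0.10), FANCA (-0.79 ± 0.09) and BRCA2 (-0.88 ± 0.12) fell. Of the 30 homologous recombination and Fanconi genes 0 rose, 15 fell and 15 did not pass, with 1 up and 19 down adjusted over the list alone. The homologous recombination and Fanconi list had a median of -0.50 (camera adjusted p = 6.10e-09, adjusted p = 0.0538 with an estimated correlation). RAD9A (-0.68 ± 0.09) and CLSPN (-0.69 ± 0.12), which act in the checkpoint at stalled forks, fell. Of the 23 checkpoint signalling genes 0 rose, 9 fell and 14 did not pass, with 0 up and 10 down adjusted over the list alone. The checkpoint signalling list had a median of -0.26 (camera adjusted p = 0.00158). RIF1, which shields broken ends, fell (-0.81 ± 0.14) and the end-binding XRCC6 rose (0.38 ± 0.08). Of the 17 end joining genes 1 rose, 1 fell and 15 did not pass, with 1 up and 1 down adjusted over the list alone. The end joining list had a median of -0.07 (camera adjusted p = 0.838). The proapoptotic BAK1 (0.79 ± 0.08) and BIK (0.65 ± 0.12) rose. Of the 28 apoptosis genes 10 rose, 1 fell and 17 did not pass, with 11 up and 4 down adjusted over the list alone. The apoptosis list had a median of 0.23 (camera adjusted p = 0.0220, adjusted p = 0.0538 with an estimated correlation). Checkpoint signalling genes had a median of -0.13 without control 2. Apoptosis genes had a median of 0.11 without the filter, and lost their call with a filter of 5 FPKM (adjusted p = 0.117).

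Tumour cell signals that act on macrophages included genes that rose and genes that fell. The secreted WNT7B (0.64 ± 0.13) and GAS6 (0.42 ± 0.10) rose, and calreticulin CALR, a signal for uptake when exposed on dying cells, fell from 793 ± 130.4 to 465 ± 46.7 FPKM (-0.76 ± 0.12). Of the 12 macrophage-directed signal genes 3 rose, 2 fell and 7 did not pass, with 4 up and 2 down adjusted over the list alone. The macrophage-directed signal list had a median of 0.25 (camera adjusted p = 0.192). The other 19 of its members, with SPP1 at 0.974 FPKM as the highest, were below the expression filter. The neutrophil chemokines CXCL8 (-1.35 ± 0.22) and CXCL1 (-0.97 ± 0.15) fell and BIRC3 rose (0.85 ± 0.19). Of the 16 NF-kB target and cytokine genes 5 rose, 2 fell and 9 did not pass, with 8 up and 2 down adjusted over the list alone. The NF-kB target and cytokine list had a median of 0.28 (camera adjusted p = 0.0928). ANGPTL4 (2.04 ± 0.18) and urokinase PLAU (0.80 ± 0.10) rose. Of the 17 senescence-associated genes 10 rose, 2 fell and 5 did not pass, with 10 up and 3 down adjusted over the list alone. The senescence-associated list had a median of 0.52 (camera adjusted p = 1.12e-04, adjusted p = 0.0538 with an estimated correlation). The peptide loading factor TAPBP (0.86 ± 0.12) and the immune ligand ULBP2 (0.68 ± 0.09) rose and PDIA3 (-0.66 ± 0.08) fell. Of the 22 antigen presentation genes 8 rose, 3 fell and 11 did not pass, with 8 up and 3 down adjusted over the list alone. The antigen presentation list had a median of 0.22 (camera adjusted p = 0.0768). The epithelial splicing factor ESRP1 fell (-0.81 ± 0.11). Of the 21 epithelial-mesenchymal transition genes 4 rose, 5 fell and 12 did not pass, with 4 up and 6 down adjusted over the list alone. The epithelial-mesenchymal transition list had a median of -0.01 (camera adjusted p = 0.742). The drug exporters ABCC3 (-0.55 ± 0.11) and ABCC2 (-0.34 ± 0.07) fell. Of the 8 paclitaxel transport genes 1 rose, 2 fell and 5 did not pass, with 1 up and 2 down adjusted over the list alone. The paclitaxel transport list had a median of -0.06 (camera adjusted p = 0.477). Senescence-associated genes had a median of 0.16 without the filter.

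The biliary keratins KRT19 (1.35 ± 0.12) and KRT18 (0.82 ± 0.14) rose. Of the 11 biliary epithelial genes 6 rose, 1 fell and 4 did not pass, with 7 up and 1 down adjusted over the list alone. The biliary epithelial list had a median of 0.49 (camera adjusted p = 0.00210, adjusted p = 0.0538 with an estimated correlation). LDHA rose (0.79 ± 0.11) and hexokinase HK2 fell (-0.75 ± 0.08). Of the 25 hypoxia and glycolysis genes 13 rose, 1 fell and 11 did not pass, with 16 up and 2 down adjusted over the list alone. The hypoxia and glycolysis list had a median of 0.37 (camera adjusted p = 1.00e-04). The remaining lists were cholesterol synthesis genes (10 rose, 0 fell, median 0.29, camera adjusted p = 0.00201), heat shock genes (5 rose, 0 fell, median 0.27, camera adjusted p = 0.00290, adjusted p = 0.130 with an estimated correlation), oxidative stress response genes (6 rose, 2 fell, median 0.13, camera adjusted p = 0.0894) and mitochondrially encoded mRNA genes (0 rose, 0 fell, median 0.03, camera adjusted p = 0.815, mean 0.01, camera direction down). For cytosolic ribosomal protein genes (0 rose, 2 fell, median -0.11, camera adjusted p = 0.0109, adjusted p = 0.618 with an estimated correlation) the call was lost without control 1 (adjusted p = 0.211) or combination 2 (adjusted p = 0.210). The 10 largest rises included KRTAP2-3 (2.21 ± 0.13), SFN (2.09 ± 0.16), CPA4 (2.04 ± 0.10), CYP24A1 (1.78 ± 0.08) and SMN1 (1.57 ± 0.16). KRTAP2-3 and SMN1 have near-identical copies and are uncertain. The cytokine receptor IL20RB was the 1 protein-coding gene among the 10 largest falls (-1.77 ± 0.15). Biliary epithelial genes had a median of 0.03 without the filter. Cytosolic ribosomal protein genes had a median of -0.17 without control 2, and lost their call by fry (adjusted p = 0.294).

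In total 3111 genes changed in the combination, 1666 higher and 1445 lower, of which 198 by at least 1 on the log2 scale. The 53.6% that were higher became 47.6% under TPM scaling. The number was 1964 without combination 3 and 2018 with a filter of 5 FPKM. It was 5049 without the 3 deviating libraries, chosen after seeing the data. Across the 4 groups the moderated F test called 3444 genes, and 2268 without radiation 1.

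**Figure D3:**
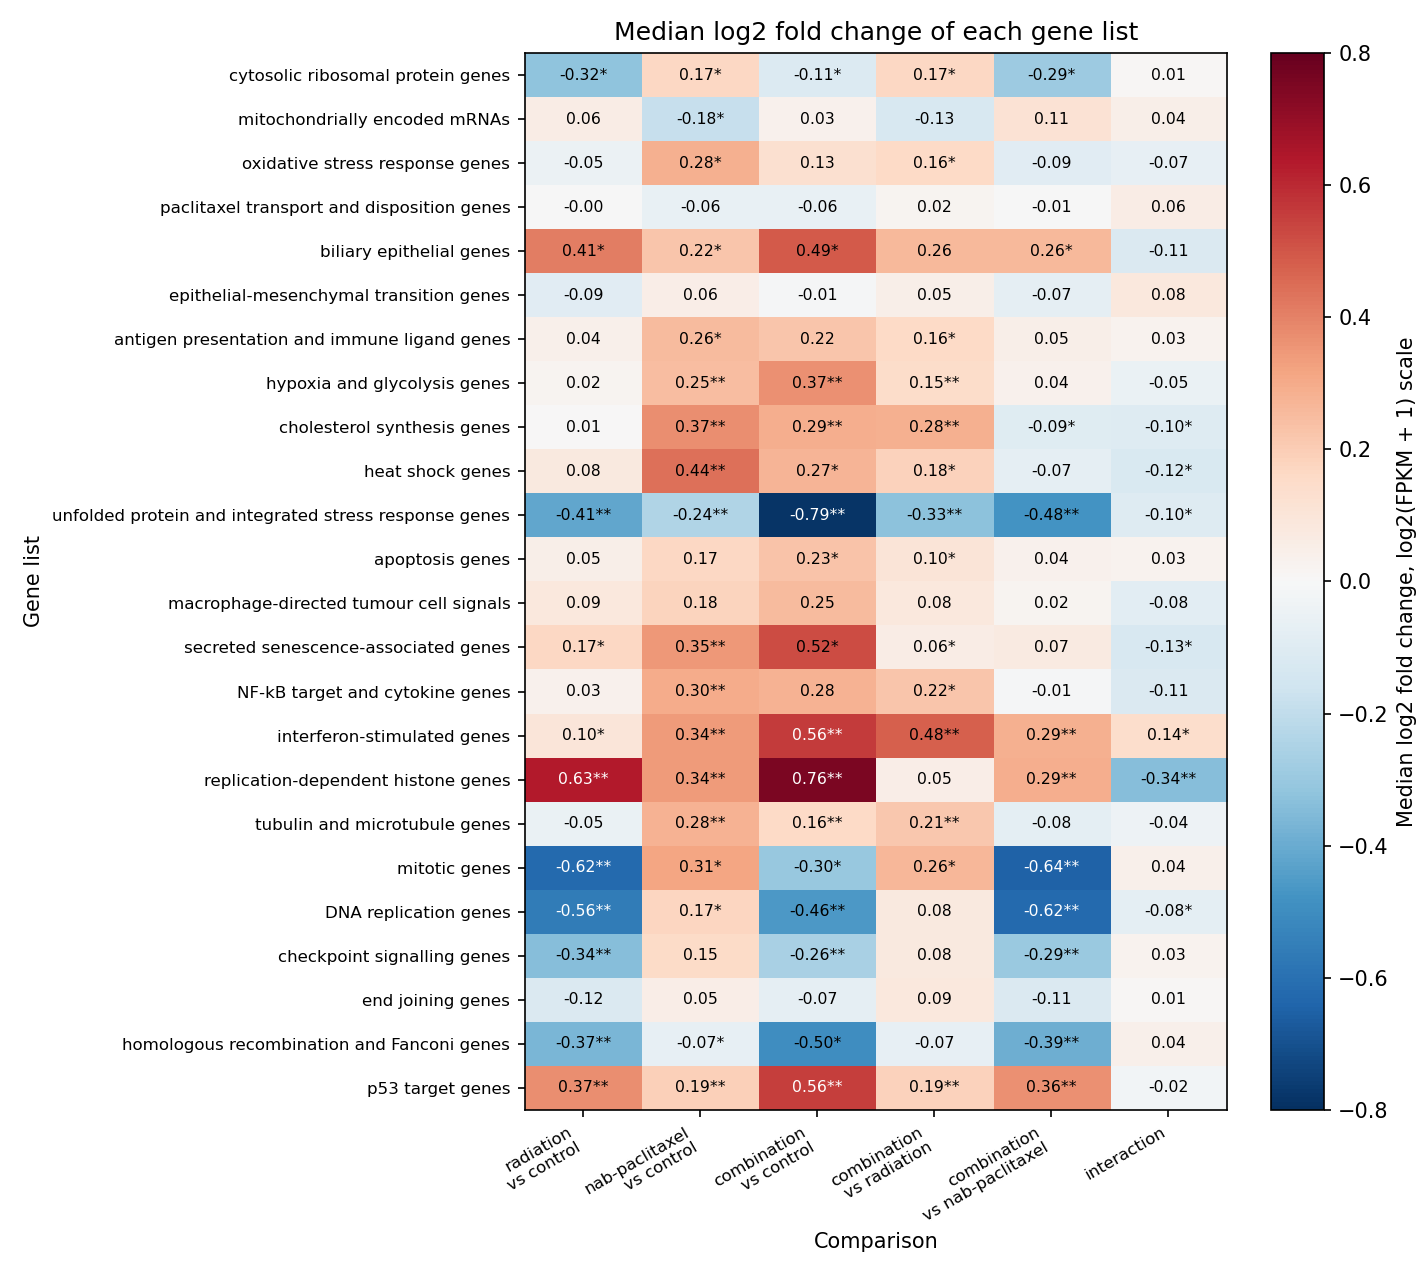
Median log2 fold change (colour and number) of 24 gene lists (vertical axis) in the 5 comparisons and the interaction (horizontal axis), where 1 star marks camera adjusted p under 0.05 with the preset correlation and 2 stars that the call also held with an estimated correlation. p53 target genes are above 0 and stress response genes below 0 in all 5 comparisons, and mitotic and replication genes are below 0 wherever irradiated libraries are set against non-irradiated ones.

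The combination against radiation, the comparison closest to the radiosensitization question, gives what the drug added in irradiated cells. OASL went from 5.09 ± 0.174 to 11.1 ± 0.352 FPKM (0.99 ± 0.08, adjusted p = 2.37e-04). TUBB rose by 0.76 ± 0.07 (adjusted p = 4.05e-04) and CDKN1A by 0.75 ± 0.08 (adjusted p = 6.47e-04). PDIA4 fell from 554 ± 4.72 to 352 ± 20.9 FPKM (-0.65 ± 0.08, adjusted p = 0.00176).

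ISG15 (1.03 ± 0.15), IFIT2 (0.78 ± 0.09) and the interferon-induced membrane protein gene IFITM2 (0.98 ± 0.10) rose. Of the 29 interferon-stimulated genes 15 rose, 0 fell and 14 did not pass, with 22 up and 0 down adjusted over the list alone. The interferon-stimulated list had a median of 0.48 (camera adjusted p = 4.18e-12). FDXR (0.74 ± 0.10) and the polo-like kinase PLK3 (0.61 ± 0.08) rose. Of the 37 p53 target genes 6 rose, 0 fell and 31 did not pass, with 8 up and 1 down adjusted over the list alone. The p53 target list had a median of 0.19 (camera adjusted p = 7.74e-04). TUBA1C (0.92 ± 0.09) and TUBA1B (0.80 ± 0.11) rose. Of the 27 tubulin and microtubule genes 9 rose, 1 fell and 17 did not pass, with 12 up and 1 down adjusted over the list alone. The tubulin and microtubule list had a median of 0.21 (camera adjusted p = 2.73e-04). The 10 alpha- and beta-tubulin genes had a median of 0.63 against 0.07 for the other 17. CDC20 (0.85 ± 0.08), cyclin CCNB2 (0.74 ± 0.10) and UBE2C (0.72 ± 0.11) were higher than with radiation alone. Of the 40 mitotic genes 13 rose, 0 fell and 27 did not pass, with 18 up and 0 down adjusted over the list alone. The mitotic list had a median of 0.26 (camera adjusted p = 4.88e-06, adjusted p = 0.189 with an estimated correlation). ASNS (-0.76 ± 0.12), TRIB3 (-0.61 ± 0.10) and DNAJB11 (-0.44 ± 0.07) fell. Of the 29 unfolded protein and integrated stress response genes 0 rose, 11 fell and 18 did not pass, with 0 up and 17 down adjusted over the list alone. This list had a median of -0.33 (camera adjusted p = 8.45e-11). FDFT1 rose (0.77 ± 0.08). Of the 26 cholesterol synthesis genes 6 rose, 0 fell and 20 did not pass, with 9 up and 0 down adjusted over the list alone. The cholesterol synthesis list had a median of 0.28 (camera adjusted p = 1.04e-04). LDHA (0.70 ± 0.11) and PGK1 (0.48 ± 0.08) rose. Of the 25 hypoxia and glycolysis genes 8 rose, 0 fell and 17 did not pass, with 11 up and 0 down adjusted over the list alone. The hypoxia and glycolysis list had a median of 0.15 (camera adjusted p = 9.50e-05). Repair and replication lists did not pass: homologous recombination and Fanconi genes (0 rose, 0 fell, median -0.07, camera adjusted p = 0.183) and DNA replication genes (6 rose, 1 fell, median 0.08, camera adjusted p = 0.141). Interferon-stimulated genes had a median of 0.29 without the filter. The p53 target genes lost their call with a filter of 5 FPKM (adjusted p = 0.0693). Tubulin and microtubule genes had a median of 0.13 under quantile scaling. Unfolded protein and integrated stress response genes had a median of -0.52 under quantile scaling. Hypoxia and glycolysis genes had a median of 0.31 with a filter of 5 FPKM.

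PLAU (0.96 ± 0.10), PLAUR (0.82 ± 0.12) and ANGPTL4 (1.23 ± 0.18) rose. Further lists past the threshold were senescence-associated genes (4 rose, 0 fell, median 0.06, camera adjusted p = 0.0130, adjusted p = 0.224 with an estimated correlation), heat shock genes (2 rose, 0 fell, median 0.18, camera adjusted p = 0.00883, adjusted p = 0.224 with an estimated correlation) and oxidative stress response genes (7 rose, 1 fell, median 0.16, camera adjusted p = 0.00112, adjusted p = 0.189 with an estimated correlation). Apoptosis genes, with BAK1 higher (0.52 ± 0.08), had a median of 0.10 (camera adjusted p = 0.0349, adjusted p = 0.101 with an estimated correlation), a call lost without combination 1 (adjusted p = 0.0506). NF-kB targets had a median of 0.22 (camera adjusted p = 0.0349, adjusted p = 0.189 with an estimated correlation), lost without nab-paclitaxel 1 (adjusted p = 0.0599) or combination 3 (adjusted p = 0.0739). Antigen presentation genes, with TAPBP higher (0.79 ± 0.12), had a median of 0.16 (camera adjusted p = 0.0424, adjusted p = 0.367 with an estimated correlation). That call was lost without radiation 1, nab-paclitaxel 1, combination 1 or combination 3 (adjusted p = 0.0519, 0.0531, 0.0607 and 0.0873). Ribosomal protein genes had a median of 0.17 (camera adjusted p = 0.00187, adjusted p = 0.592 with an estimated correlation), which was -0.04 under quantile normalization. Quantile normalization ended the calls for p53 target (adjusted p = 0.129), heat shock (adjusted p = 0.329), senescence-associated (adjusted p = 0.338), oxidative stress (adjusted p = 0.129), apoptosis (adjusted p = 0.129), NF-kB (adjusted p = 0.0686) and antigen presentation genes (adjusted p = 0.379). Senescence-associated genes had a median of 0.03 with tested-gene size factors, 0.03 under TPM scaling, 0.12 without the 3 deviating libraries, 0.09 without radiation 2, 0.10 without radiation 3 and 0.12 without combination 2. The senescence-associated genes lost their call with a filter of 5 FPKM and by camera on ranks (adjusted p = 0.110 and 0.0610). Heat shock genes lost their call with a filter of 5 FPKM (adjusted p = 0.0733). Apoptosis genes had a median of 0.06 with tested-gene size factors, 0.05 under TPM scaling, 0.18 without the 3 deviating libraries and 0.18 without combination 2. The apoptosis genes lost their call with a filter of 5 FPKM, among protein-coding genes and by camera on ranks (adjusted p = 0.226, 0.0964 and 0.0610). NF-kB target and cytokine genes had a median of 0.02 without the filter, and lost their call with a filter of 5 FPKM, under TPM scaling and among protein-coding genes (adjusted p = 0.171, 0.0801 and 0.0779). Antigen presentation genes lost their call with a filter of 5 FPKM, under TPM scaling, among protein-coding genes and by camera on ranks (adjusted p = 0.262, 0.0801, 0.0949 and 0.0610). Cytosolic ribosomal protein genes lost their call with a filter of 5 FPKM and by fry (adjusted p = 0.0997 and 0.186).

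Large rises outside the lists were those of SFN (1.35 ± 0.16), the arrestin-like ARRDC4 (1.28 ± 0.12), the hyaluronan synthase HAS3 (0.93 ± 0.11) and SMN1 (1.62 ± 0.16), which is uncertain for its copy SMN2. The 10 largest falls were small RNA genes, pseudogenes or an antisense gene, such as RNU1-138P (-1.60 ± 0.27). In total 1055 genes changed with the drug in irradiated cells, 654 higher and 401 lower, of which 42 by at least 1 on the log2 scale. The 62.0% that were higher became 50.9% with size factors from the tested genes. The number of genes was 248, 287 and 301 without radiation 1, 2 and 3, 383, 703 and 218 without combination 1, 2 and 3, and 1879 without nab-paclitaxel 1. It was 577 without the expression filter and 2502 with only these 2 groups in the fit. It was 4128 without the 3 deviating libraries, chosen after seeing the data.

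The combination against nab-paclitaxel gives what radiation added in drug-treated cells. MCM3 fell from 36.0 ± 1.95 to 19.1 ± 1.03 FPKM (-0.89 ± 0.08, adjusted p = 3.56e-04), and E2F1 fell too (-1.13 ± 0.11, adjusted p = 6.47e-04). CDKN1A rose by 0.78 ± 0.08 (adjusted p = 7.32e-04). PINCR, a long noncoding RNA of the p53 response, rose from 1.53 ± 0.266 to 5.65 ± 0.285 FPKM (1.40 ± 0.10, adjusted p = 1.51e-04).

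CDT1 (-1.11 ± 0.11) and RRM2 (-1.14 ± 0.16) fell. Of the 39 DNA replication genes 0 rose, 31 fell and 8 did not pass, with 0 up and 37 down adjusted over the list alone. The DNA replication list had a median of -0.62 (camera adjusted p = 2.75e-37). BIRC5 (-0.97 ± 0.09), the checkpoint kinase BUB1B (-0.76 ± 0.08) and the spindle factor TPX2 (-0.64 ± 0.07) fell. Of the 40 mitotic genes 0 rose, 26 fell and 14 did not pass, with 0 up and 36 down adjusted over the list alone. The mitotic list had a median of -0.64 (camera adjusted p = 2.89e-32). The exonuclease EXO1 (-0.63 ± 0.09) and RAD54L (-0.73 ± 0.11) fell. Of the 30 homologous recombination and Fanconi genes 0 rose, 11 fell and 19 did not pass, with 0 up and 15 down adjusted over the list alone. The homologous recombination and Fanconi list had a median of -0.39 (camera adjusted p = 4.15e-11). H2AFX, the histone variant phosphorylated at DNA breaks, fell (-0.73 ± 0.10). Of the 23 checkpoint signalling genes 0 rose, 7 fell and 16 did not pass, with 0 up and 11 down adjusted over the list alone. The checkpoint signalling list had a median of -0.29 (camera adjusted p = 2.84e-07). TP53INP1 (0.99 ± 0.11) and PLK3 (0.68 ± 0.08) rose. Of the 37 p53 target genes 13 rose, 0 fell and 24 did not pass, with 19 up and 1 down adjusted over the list alone. The p53 target list had a median of 0.36 (camera adjusted p = 1.62e-17). HERPUD1 (-0.71 ± 0.09) and TRIB3 (-0.89 ± 0.10) fell. Of the 29 unfolded protein and integrated stress response genes 0 rose, 17 fell and 12 did not pass, with 1 up and 22 down adjusted over the list alone. This list had a median of -0.48 (camera adjusted p = 7.32e-19). HIST1H2BD (0.72 ± 0.09) and OASL (0.99 ± 0.08) rose. Of the 11 replication-dependent histone genes 3 rose, 0 fell and 8 did not pass, with 8 up and 0 down adjusted over the list alone. The replication-dependent histone list had a median of 0.29 (camera adjusted p = 2.68e-07). Of the 29 interferon-stimulated genes 4 rose, 0 fell and 25 did not pass, with 14 up and 0 down adjusted over the list alone. The interferon-stimulated list had a median of 0.29 (camera adjusted p = 8.90e-09). CXCL1 (-1.25 ± 0.15) and CXCL8 (-1.26 ± 0.22) fell. Replication-dependent histone genes had a median of 0.49 with a pseudocount of 0.1, 0.13 without the filter, 0.44 with a filter of 5 FPKM and 0.50 by voom. Interferon-stimulated genes had a median of 0.12 without the filter and 0.15 with a filter of 5 FPKM.

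Ribosomal protein genes had a median of -0.29 (camera adjusted p = 1.90e-12, adjusted p = 0.230 with an estimated correlation). Cholesterol synthesis genes had a median of -0.09 (camera adjusted p = 0.0445, adjusted p = 0.139 with an estimated correlation), a call lost without nab-paclitaxel 2, nab-paclitaxel 3 or combination 2 (adjusted p = 0.0929, 0.0568 and 0.129). Biliary genes had a median of 0.26 (camera adjusted p = 0.0363, adjusted p = 0.170 with an estimated correlation), lost without nab-paclitaxel 2 or 3 or combination 1 or 3 (adjusted p = 0.0586, 0.122, 0.0824 and 0.0573). TUBB fell (-0.45 ± 0.07), while the tubulin and microtubule list had a median of -0.08 and did not pass (camera adjusted p = 0.0947). In total 533 genes changed with radiation in drug-treated cells, 165 higher and 368 lower, of which 22 by at least 1 on the log2 scale. The 30.96% that were higher became 41.8% under quantile normalization. The number of genes was 323, 341 and 334 without radiation 1, 2 and 3, 323 and 332 without nab-paclitaxel 2 and 3, and 274, 284 and 177 without combination 1, 2 and 3. It was 93 with only these 2 groups in the fit and 276 without the expression filter. It was 1301 without the 3 deviating libraries, chosen after seeing the data. Cytosolic ribosomal protein genes had a median of -0.12 under quantile scaling, -0.12 without the 3 deviating libraries and -0.17 without nab-paclitaxel 1. Cholesterol synthesis genes had a median of -0.15 without nab-paclitaxel 1, and lost their call with a filter of 5 FPKM, under quantile scaling and among protein-coding genes (adjusted p = 0.0684, 0.0647 and 0.0630). Biliary epithelial genes had a median of 0.03 without the filter, and lost their call without the filter, with a filter of 5 FPKM and by camera on ranks (adjusted p = 0.503, 0.104 and 0.0699).

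The interaction, the radiation effect with drug minus that without it, tests whether the treatments acted additively on the log2 scale. For single genes limma called 0, with 443 genes at an unadjusted p under 0.05 where 680 would be expected by chance, and voom on recovered fragments called 0. Without the expression filter limma called 5. The 95% interval of a gene's interaction reached a median of 0.39 to either side. In simulated data limma recovered 0 of 13 interactions of 0.5, 5 of 14 of 1 and 8 of 13 of 2. The genes with the smallest p, none past the threshold, included SMN1 (1.23 ± 0.22), CYR61 (-0.82 ± 0.16), CTGF (-0.76 ± 0.15) and TNFSF9 (-0.57 ± 0.12), each at adjusted p = 0.989. CDKN1A was at 0.01 ± 0.11.

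The radiation effects without and with drug correlated across genes with Pearson r = 0.578 and Spearman rho = 0.618. All 358 genes called in both had the same sign, 102 higher and 256 lower. If the calls were independent across genes, 4.09 and 12.7 would be expected. For the drug effects without and with radiation r was 0.683 and rho 0.730. Without the expression filter rho was 0.364 for radiation and 0.477 for the drug. All 594 genes called in both had the same sign, 395 higher and 199 lower, against 35.4 and 13.7 expected. The effects of each pair share no library, and genes are not independent replicates, so no p is given.

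As a group, the 11 tested of 25 histone genes departed from additivity with either correlation, rising less after radiation with drug than without. HIST1H1C (-0.45 ± 0.16) and HIST1H2BK (-0.39 ± 0.13) did not pass on their own. Of the 11 replication-dependent histone genes 0 rose, 0 fell and 11 did not pass, with 0 up and 4 down adjusted over the list alone. The replication-dependent histone list had a median of -0.34 (camera adjusted p = 9.33e-07). The camera calls of 6 more lists were lost with an estimated correlation and by fry. They were those of interferon-stimulated genes (median 0.14, camera adjusted p = 1.64e-04, adjusted p = 0.122 with an estimated correlation), heat shock genes (median -0.12, camera adjusted p = 0.00534, adjusted p = 0.261 with an estimated correlation) and senescence-associated genes (median -0.13, camera adjusted p = 0.0103, adjusted p = 0.261 with an estimated correlation). The others were replication genes (median -0.08, camera adjusted p = 0.0122, adjusted p = 0.261 with an estimated correlation), stress response genes (median -0.10, camera adjusted p = 0.0314, adjusted p = 0.261 with an estimated correlation) and cholesterol synthesis genes (median -0.10, camera adjusted p = 0.0349, adjusted p = 0.261 with an estimated correlation). Of these, the calls for heat shock, senescence-associated, replication, stress response and cholesterol synthesis genes were lost without nab-paclitaxel 1 (adjusted p = 0.214, 0.180, 0.180, 0.180 and 0.0947). Those other than heat shock were also lost without combination 2 (adjusted p = 0.0881, 0.0536, 0.130 and 0.130). Without control 2 the senescence-associated, stress response and cholesterol calls were lost (adjusted p = 0.0801, 0.171 and 0.210). Without control 3 the replication and stress response calls were lost (adjusted p = 0.0833 and 0.0661). Without radiation 2 or nab-paclitaxel 2 the stress response (adjusted p = 0.0887 and 0.0562) and cholesterol calls (adjusted p = 0.0962 and 0.0802) were lost. The cholesterol call was lost without radiation 3 (adjusted p = 0.0700) and the stress response call without combination 3 (adjusted p = 0.0579). p53 target genes were not called (median -0.02, camera adjusted p = 0.717). Interferon-stimulated genes had a median of 0.06 without the filter and 0.05 with a filter of 5 FPKM. Heat shock genes had a median of -0.05 without control 3 and -0.19 without nab-paclitaxel 3, and lost their call without the 3 deviating libraries (adjusted p = 0.218). Senescence-associated genes lost their call without the 3 deviating libraries and by camera on ranks (adjusted p = 0.575 and 0.163). DNA replication genes lost their call under quantile scaling and without the 3 deviating libraries (adjusted p = 0.188 and 0.421). Stress response genes had a median of -0.15 without nab-paclitaxel 3. Their call was lost without the filter, without the 3 deviating libraries and by camera on ranks (adjusted p = 0.132, 0.575 and 0.0792). Cholesterol synthesis genes lost their call without the filter and without the 3 deviating libraries (adjusted p = 0.102 and 0.328).

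**Figure D4:**
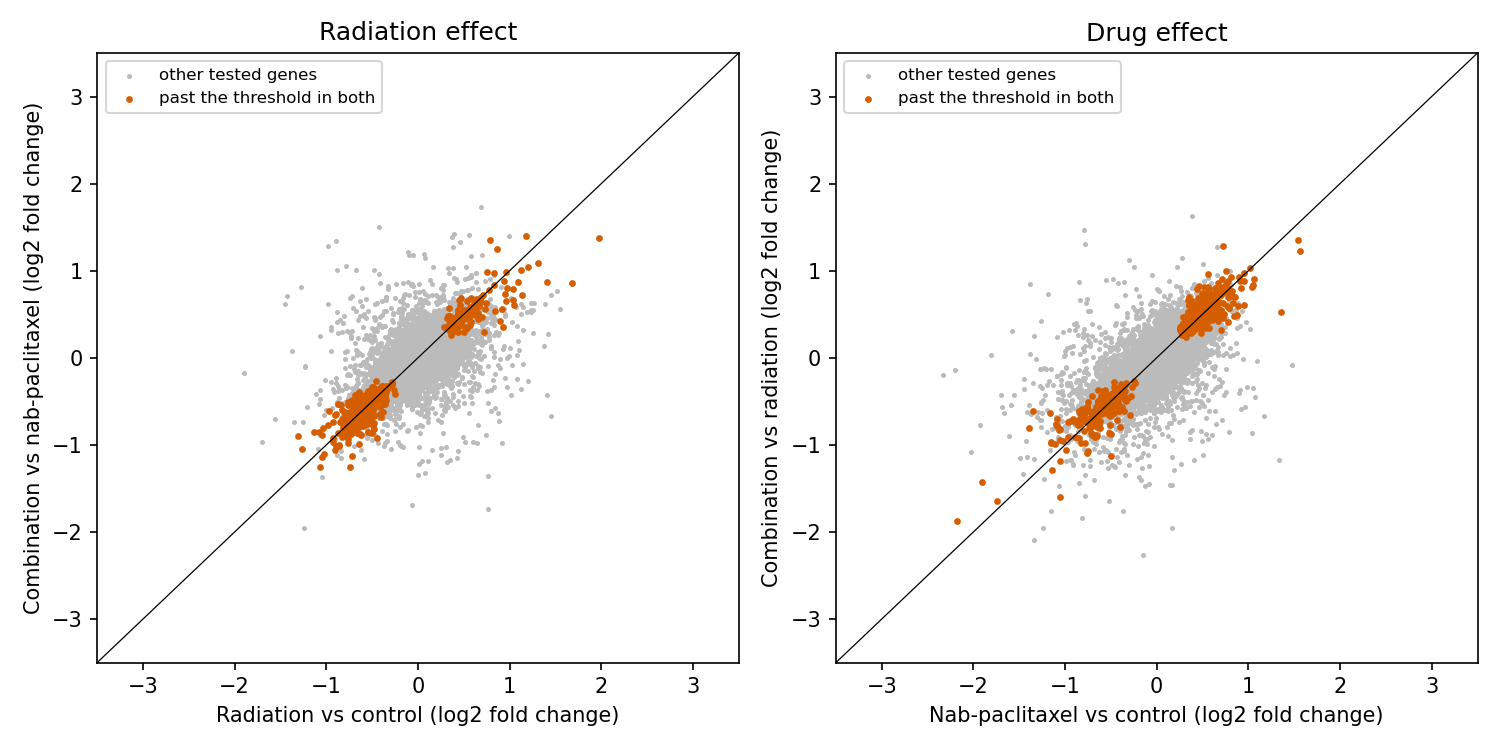
Log2 fold changes of the 13609 tested genes, with radiation vs control against combination vs nab-paclitaxel on the left and nab-paclitaxel vs control against combination vs radiation on the right. Orange points are genes past the threshold in both (358 and 594), the line marks equal effects, and every orange point lies in a quadrant of equal sign.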

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

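Of the tests in this part, those of sequencing depth, more mitotic cells, scaling for tubulin, tubulin mRNA regulation, denser control cultures and the regroupings for the interaction were chosen after the result was seen. The GC correction and the removal of the 3 libraries were also chosen after seeing the data.

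For 7 gene lists camera called a difference of the radiation effect between cells with and without drug, but for 6 of them the call was lost with an estimated correlation and by fry, and for 5 without nab-paclitaxel 1. The call that held was that of histone genes, with a median difference of -0.3413 (camera adjusted p = 9.33e-07, adjusted p = 0.0101 with an estimated correlation). Medians of the other lists follow, with the adjusted p by camera and then with an estimated correlation. They were 0.1392 for interferon-stimulated genes (adjusted p = 0.000164, then 0.122) and -0.1205 for heat shock genes (adjusted p = 0.00534, then 0.261). They were -0.1291 for senescence-associated genes (adjusted p = 0.0103, then 0.261) and -0.07729 for DNA replication genes (adjusted p = 0.0122, then 0.261). They were -0.1013 for stress response genes (adjusted p = 0.0314, then 0.261) and -0.1009 for cholesterol synthesis genes (adjusted p = 0.0349, then 0.261). Limma called 0 single genes in the interaction (443 at an unadjusted p under 0.05, and 0 by voom).

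Control 2, nab-paclitaxel 1 and combination 2 deviated together from their groups. Sequencing depth is argued against: control 2 was the deepest of its group, the other 2 the shallowest of theirs, yet all 3 deviated together. The proliferation state of the cultures stays open: the mitotic list lay outside matched random lists in 1 of the 3 only, which cannot exclude it. Gene length decided nothing, with rho 0.12 in control 2, -0.13 in nab-paclitaxel 1 and 0.16 in combination 2. GC content of genes may be involved, with rho with the deviation of -0.74, -0.47 and -0.67 in the same order. Each library also had the fewest genes above 0 of its group (26352, 24214 and 26657) and the highest mitochondrial mRNA share. What made the libraries differ in these and in GC stays open. The labels give no batch.

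Of the 10 alpha- and beta-tubulin mRNAs 9 rose in nab-paclitaxel vs control (median 0.79, SE 0.12 over the 10 genes) and 7 in combination vs radiation (median 0.63), and the others did not pass. The mitotic list rose in both drug comparisons as well, with a median of 0.31 in nab-paclitaxel vs control and 0.26 in combination vs radiation (adjusted p = 0.147 and 0.189 with an estimated correlation), so more mitotic cells stay open as a part of the source. As the whole source they are argued against by a tubulin median of 0.63 (SE 0.16 over 10 genes) in combination vs control, which also holds the radiation effect and where the mitotic list fell (median -0.30, adjusted p = 0.0951 with an estimated correlation). The 3 deviating libraries, GC content and scaling are argued against as the whole source by medians in nab-paclitaxel vs control of 0.71 without those libraries, 0.74 after GC correction and 0.63 under quantile normalization, the smaller of that and TPM scaling. Regulation of tubulin mRNA by the drug stays open too: the tubulin genes exceeded the other genes of their list by at least 0.56 in both drug comparisons, but this restates the pattern, since the subset was chosen after its rise was seen.

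Endoplasmic reticulum and integrated stress response genes fell in the combination, with a median of -0.79 (SE 0.10 over 29 genes) against control. Scaling is argued against by -0.84 under TPM and quantile scaling, the 3 deviating libraries by -0.76 without them, and GC content by -0.77 after correction. Denser, nutrient-poor cultures in control alone are argued against as the whole source by -0.33 (SE 0.06) against radiation and -0.48 (SE 0.07) against nab-paclitaxel. Density falling from control to combination would give these too and stays open, as does control alone as a part. Either would lower hypoxia and glycolysis genes in the combination (median 0.37), but the drug alone raised these (0.25), masking a fall. In radiation vs control their median of 0.02 (SE 0.06 over 25 genes) decides nothing.

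Each pairwise comparison has 10 splits of its 6 libraries, too few for a share under 0.05. The real split gave 807 genes for radiation vs control against at most 1 in another split, and 1 split of 10 gave as many. For nab-paclitaxel vs control (1200), combination vs control (3111), combination vs radiation (1055) and combination vs nab-paclitaxel (533) the highest other split gave 0. For the F test 1 of 100 regroupings of the 12 libraries, the real one, reached 3444 genes and the highest other gave 230. Chance is thus argued against, though a share of 1 in 100 cannot exclude it. For the interaction the number found was 0, which 100 of 100 regroupings reach whatever the data, so nothing follows about chance, and the highest other gave 808. So many genes in a regrouping point to a structure of the samples, since regrouped libraries still carry the treatment effects.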

How the results depend on the processing

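The settings without the 3 deviating libraries, with the principal component of the deviations as a covariate, with GC correction and with library weights were chosen after seeing the data. Except where the construction of a setting shows it, the cause was not tested.

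Gene lists kept direction and side of the threshold in 3788 of 4176 results across settings. They were no longer past it in 155, newly past it in 91 and reversed in 4, and the other 138 were uncalled medians that changed sign. For named genes the numbers were 12355 the same of 13464, 908 no longer past, 38 newly past, 0 reversed and 163 uncalled that changed sign. The reversed medians were those of ribosomal protein genes, -0.0258 in nab-paclitaxel vs control and -0.0388 in combination vs radiation under quantile normalization and -0.0144 in nab-paclitaxel vs control with library weights, and of senescence-associated genes in the interaction, 0.0305 with library weights.

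With every gene above 0 tested, 579 genes changed in nab-paclitaxel vs control, 577 in combination vs radiation, 276 in combination vs nab-paclitaxel and 5 in the interaction. The correlations then were r 0.392 and rho 0.364 for radiation and r 0.509 and rho 0.477 for the drug. With a mean of at least 5 FPKM, 2018 genes changed in combination vs control, where fewer genes are tested, and 7 lists were called in combination vs radiation. The correlations were r 0.741 and rho 0.723 for radiation and r 0.786 for the drug. A pseudocount of 0.1 gave r 0.429 for radiation and 0.574 for the drug, and TPM scaling r 0.505 for radiation. Quantile normalization gave 789 genes in nab-paclitaxel vs control and 6 lists in combination vs radiation.

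The replicate numbers as a block gave 531 genes in radiation vs control, 701 in nab-paclitaxel vs control, 606 in combination vs radiation and 306 in combination vs nab-paclitaxel. In combination vs control it gave 2660 genes and changed no list call there, and of the named genes' calls only that of MIR25 (adjusted p = 0.0630). Deviations of libraries with the same number correlated above 0.1 in 5 of 18 pairs, over a range of -0.49 to 0.54, and 3 of the 5 are the pairs of control and combination. In the other comparisons not every pair did, so there the block spends degrees of freedom on numbers that did not pair the samples.

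In the order radiation vs control, nab-paclitaxel vs control, combination vs control, combination vs radiation, combination vs nab-paclitaxel and the F test, the genes were 2947, 1836, 5049, 4128, 1301 and 6227 without the 3 deviating libraries, with 3 lists called in the interaction. They were 3010, 4359, 5964, 4058, 2378 and 7513 with the component as a covariate, with 2 genes in the interaction. They were 2105, 3050, 5142, 2888, 1632 and 6121 after GC correction, and 3469, 2826, 5560, 5013, 2468 and 7668 with library weights, with 4 genes and 3 lists in the interaction. The covariate, the weights and the removal use the deviations that they take out, so they raise these numbers partly by construction. With only the 2 groups compared in the fit, 8 genes changed in nab-paclitaxel vs control, 2502 in combination vs radiation and 93 in combination vs nab-paclitaxel, where the spread rests on 4 residual degrees of freedom. In the settings not named here with a number, the interaction called 0 genes.

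With an estimated correlation camera called 7 lists in radiation vs control, 10 in nab-paclitaxel vs control, 9 in combination vs control, 6 in combination vs radiation and 1 in the interaction. The set test fry, which asks whether a list moves one way and does not set it against other genes, called 17 in combination vs nab-paclitaxel and 1 in the interaction.

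Leaving out each library in turn gave 320 to 1305 genes in radiation vs control, 524 to 1181 in nab-paclitaxel vs control, 1964 to 3926 in combination vs control, 218 to 1879 in combination vs radiation, 177 to 734 in combination vs nab-paclitaxel, 0 to 0 in the interaction and 2268 to 3890 in the F test. In the same order of comparisons, the lists called were 11 to 12, 15 to 18, 16 to 16, 12 to 17, 10 to 13 and 3 to 8. The radiation correlations were r 0.506 to 0.576 and rho 0.527 to 0.620, and the drug correlations r 0.597 to 0.688 and rho 0.629 to 0.742. Fragments per library, 14840283 to 17992242, limit what is seen of small RNA genes, and genes under 1 FPKM were not tested.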

Other observations

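Mitochondrial ribosomal RNA, whose level also depends on how poly(A) RNA was selected, took 2.03 ± 0.103% of fragments in control, 2.66 ± 0.0672% in radiation, 2.03 ± 0.239% in nab-paclitaxel and 2.95 ± 0.177% in the combination (mean ± SD, n = 3). Long noncoding RNA took 1.18 ± 0.0147%, 1.29 ± 0.0148%, 0.978 ± 0.0412% and 1.06 ± 0.0258% in the same order. Neither share was tested between groups.

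Of the markers of other cell types, 5 had a mean of at least 1 FPKM and were tested. In combination vs control ACTA2, smooth muscle actin and a marker of activated fibroblasts, rose (1.05 ± 0.13 on the log2 scale, SE, adjusted p = 3.15e-04) and COL1A1, a collagen chain, fell (-0.59 ± 0.09, adjusted p = 0.00128). ITGAX, an integrin of myeloid cells, TAGLN and FBLN1 did not pass there (adjusted p = 0.515, 0.686 and 0.305). ACTA2 stood at 0.964 ± 0.207 FPKM in control, 1.92 ± 0.201 in radiation, 1.52 ± 0.367 in nab-paclitaxel and 3.05 ± 0.308 in the combination (mean ± SD, n = 3). In the same order COL1A1 stood at 6.85 ± 0.665, 7.16 ± 0.421, 4.58 ± 0.171 and 4.23 ± 0.475 FPKM, ITGAX at 1.81 ± 0.153, 2.44 ± 0.106, 1.33 ± 0.304 and 2.03 ± 0.114, TAGLN at 1.59 ± 0.214, 1.97 ± 0.135, 1.31 ± 0.253 and 1.46 ± 0.340, and FBLN1 at 4.96 ± 0.635, 4.07 ± 0.608, 5.22 ± 0.447 and 4.30 ± 0.316. The fibroblast genes COL1A2 and DCN had means of 0.00219 and 0.00385 FPKM over the 12 libraries, and the macrophage genes CD68 and CD163 of 0.0162 and 0.0111 FPKM.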
